A study of Mus musculus with 18 samples.

How the data were processed

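RNA from 18 samples of mouse aorta was measured on 1-colour Affymetrix arrays. Per the labels' protocols, male C57Bl/6 mice received spironolactone at 20 mg/kg/day for 5 days, and their aortas were then kept in culture for 2, 4 or 8 h, with aldosterone at 100 nM or with vehicle. Each sample is a pool of 3 aortas, and each of the 6 groups of treatment and time holds 3 such pools, so replicates differ in animals, culture and array. The deposited values are log2 expression estimates made with GCRMA, per the submitters' processing notes; the version and settings of GCRMA are not given in the sources used here. Raw array files were not used here, and no genome coordinates are reported because no build is named in the sources used here.

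The value table held 64 Affymetrix control probe sets beside those of genes. In the annotation, 20380 probe sets belong to 1 gene, 691 to several genes and 1606 to none, controls included, and 20364 of the 1-gene probe sets matched a gene in the RefSeq table. Probe sets with 1 gene were kept where the log2 value was above 4 in at least 3 of the 18 samples, which left 11236. The probe set with the highest mean over the 18 samples stood for its gene, which gave 7092 genes, 2704 of them with more than 1 probe set past the filter. Folds of dim genes are imprecise. No detection calls were used here; where every sample of a group lay at or under 4 for a named gene, its fold is given as at least the other group's mean over that level, and such genes are not ranked. For the average over times and differences between times, such genes are given with values under 4 set to 4.

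A cell-means model of the 6 groups was fitted to all 18 samples with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step. The fit had 12 residual and 17.2 total degrees of freedom, and the median standard deviation within groups was 0.235. Comparisons were aldosterone against vehicle at 2, 4 and 8 h, the mean of these 3 differences, an F test of their differences between times, and vehicle at 8 h and 4 h against vehicle at 2 h, which share the 2 h samples. P-values were adjusted by Benjamini-Hochberg over the 7092 genes with a threshold of 0.05 and no minimum fold. With 3 arrays per group, the number of arrays limits precision. On simulated data of 7092 genes, the comparison at 8 h recovered 22.4%, 73.1% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale, with 9 false calls among 139. The comparison at 2 h made 13 false calls among 144, that at 4 h 7 among 143, the average over times 15 among 191 and the test of differences between times 3 among 96. Each is a single draw of independent normal noise, with the same spread for a gene in all 18 samples. No simulated array stood apart as vehicle 2 h replicate 1 does, so these rates may not describe the real comparison at 2 h.

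Gene lists, comparisons, tests, the filter and the rule for naming genes were set before the data were examined. The 11 pathway lists, with measured genes of those listed, were corticosteroid response (25 of 29), corticosteroid receptors and renal aldosterone response (8 of 18), metallothioneins and oxidative stress (19 of 24), immediate early (18 of 20), inflammatory mediators and adhesion (20 of 25), extracellular matrix and fibrosis (18 of 21), vascular tone and growth signalling (16 of 23), circadian clock (14 of 18), hypoxia and glycolysis (15 of 17), heat shock and unfolded protein response (16 of 16) and cell cycle (6 of 14). The cell type lists were smooth muscle (11 of 11), endothelial (10 of 11), fibroblast (8 of 8), white and brown adipocyte (7 of 11), macrophage (9 of 11), cardiac muscle (3 of 6), lymphocyte (1 of 8), Schwann cell and nerve (1 of 7), skeletal muscle (0 of 6), red blood cell (2 of 5) and mesothelial (0 of 4). Lists with at least 3 measured genes were tested with camera at a correlation between genes of 0.01, adjusted over the 17 lists within a comparison, and again with an estimated correlation and with fry. Members past the threshold were counted over all genes and adjusted over the list alone.

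Always named were 8 genes: 6 were measured (Nr3c1, Fkbp5, Tsc22d3, Per1, Sgk1 and Zbtb16), Hsd11b2 was below the filter, and 1 had no named probe set and is not reported here. Also named were the 10 largest rises and falls past the threshold at each time whose 3 aldosterone samples all lay on one side of the 3 vehicle samples, and for the average those with the same sign at each time. For differences between times the 10 smallest p-values were named, for vehicle culture the 10 largest rises and falls at 8 h and 5 at 4 h, and from each list up to 4 members with the smallest p. RNA integrity was the 3' minus 5' log2 signal of the Gapdh and beta-actin controls, compared by exact permutation within times.

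Alternatives were a prior without trend, no filter, a filter at 6, all probe sets, the mean of a gene's probe sets, quantile normalization again, median centring, array weights, a replicate term as fixed or random, a minimum fold of 1.5 with adjusted or unadjusted p, only the samples compared, and each sample left out in turn. The alternative without vehicle 2 h replicate 1 as a reported result was chosen after its divergence was seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.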

Results

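Gene expression was measured in 18 samples of mouse aorta, each a pool of 3 aortas from male C57Bl/6 animals. The animals had carried a subcutaneous pellet of spironolactone, an antagonist of the mineralocorticoid receptor (MR), at 20 mg/kg/day for 5 days, which the study used to lower MR-driven expression before hormone was added. The excised aortas were kept in organ culture with vehicle or with 100 nM aldosterone, the endogenous MR agonist, for 2, 4 or 8 h, and each of the 6 groups held 3 pools. From the array table, 7092 genes were tested. Time in culture separated the samples most: the first principal component carried 65.2% of the variance and ordered the groups by hour, and correlations between samples ran from 0.838 to 0.994. Vehicle 2 h replicate 1 stood apart, with the highest median signal of the 18 samples, the other 17 lying between 4.01 and 4.09 on the log2 scale. Relative to the mean of its 2 group mates, 908 of the 7092 genes in it were off by more than 1 on the log2 scale. In the text below, changes between 2 groups are log2 differences ± SE of 3 samples against 3, and adjusted p-values come from limma. The SE rests on 1 spread per gene, estimated over all 18 samples, so it does not show the spread of the samples compared. Averages over times and differences between times use more samples.

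The earliest comparison asks what aldosterone changed within 2 h. Chac1, an ATF4-induced enzyme that breaks down glutathione, rose at least 1.22-fold (fitted 1.38 ± 0.15, adjusted p = 0.000286). Bphl, a serine hydrolase, rose at least 1.71-fold (fitted 1.15 ± 0.19, adjusted p = 0.0237), and the zinc finger gene Zfp52 rose 1.53-fold (0.61 ± 0.09, adjusted p = 0.00805). Hes1, a transcriptional repressor downstream of Notch, fell to 0.44 of its vehicle level (-1.19 ± 0.20, adjusted p = 0.0287). Prkra, an activator of the double-stranded RNA kinase PKR, was at least 1.24-fold lower (fitted -0.89 ± 0.16, adjusted p = 0.0473). These were the only 5 of 7092 genes past the adjusted threshold, 3 higher and 2 lower, and 782 had an unadjusted p under 0.05. For all 5, the aldosterone samples lay entirely on one side of the vehicle samples. Chance gives this for 10% of unselected genes. These 5 were selected by p-value on the same samples, so it adds no separate support. Chac1 was dim at this time, at 2.91 ± 0.02 (SD, n = 3) in vehicle and 4.29 ± 0.29 (SD, n = 3) with aldosterone, and in vehicle alone it rose at least 25.7-fold between 2 and 4 h. Bphl, at 3.62 and 4.77, and Prkra, at 4.30 and 3.42, were as dim, and a second, dimmer Bphl probe set gave -0.25. In vehicle alone, Hes1 samples fell from 6.63 to 7.34 at 2 h to 4.10 to 4.56 at 4 h. Those of Zfp52 rose from 9.86 to 9.95 to 11.43 to 11.50. The aldosterone difference at 4 and 8 h was 0.09 and 0.06 for Hes1, and 0.41 and 0.57 for Zfp52. The effect at 2 h was not separated from these changes in culture.

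The always-named corticosteroid targets were not past the threshold at 2 h. Fkbp5, a co-chaperone that restrains the glucocorticoid receptor, gave 0.17 ± 0.26 (adjusted p = 0.835). Zbtb16, a zinc finger transcription factor also called PLZF, gave -0.02 ± 0.19 (adjusted p = 0.979). Sgk1, the kinase that promotes sodium channel activity in the kidney, gave 0.01 ± 0.17 (adjusted p = 0.991). Per1, a repressor of the circadian clock, gave 0.56 ± 0.26 (adjusted p = 0.429), and Tsc22d3, the glucocorticoid-induced leucine zipper, gave -0.18 ± 0.26 (adjusted p = 0.83). Nr3c1, the glucocorticoid receptor, gave -0.14 ± 0.15 (adjusted p = 0.751). Of the 25 measured corticosteroid response genes, 0 rose and 0 fell over all genes, 3 rose adjusted over the list alone, and the list median was 0.02. These values lean on vehicle 2 h replicate 1: without it the list median was 0.14 and 2 members rose over all genes, and Fkbp5 at 2 h was 0.57 without it and -0.24 without vehicle 2 h replicate 2. The list ranked above other genes by camera (adjusted p = 0.000568), with adjusted p = 0.623 when the correlation was estimated.

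Immediate early genes had a median of -0.31 at 2 h and ranked below other genes by camera (adjusted p = 0.000276), a call lost with an estimated correlation (adjusted p = 0.623). Of its 18 measured members 0 passed over all genes and 5 fell adjusted over the list alone, among them the transcription factor gene Jun at -0.54 ± 0.13 and Zfp36, an mRNA-decay factor, at -0.58 ± 0.16. With aldosterone at 2 h, inflammatory mediators and adhesion genes also ranked low (adjusted p = 0.00401, and 0.768 with an estimated correlation). In vehicle from 2 to 4 h, without vehicle 2 h replicate 1, the immediate early median was -1.50 and the inflammatory median 0.63. With aldosterone at 2 h, none of the 20 inflammatory genes passed over all genes and 4 fell adjusted over the list alone. The cytokine Tnf was at -0.86 ± 0.23 and the endothelial adhesion molecule Sele at -1.03 ± 0.30. Without vehicle 2 h replicate 1, chosen after seeing the data, 29 genes passed at 2 h, 23 higher and 6 lower. Mt1 and Mt2, zinc-binding metallothioneins, were then past the threshold, 2.19-fold and 2.01-fold higher (adjusted p = 0.00431 for each), as was the deubiquitinase gene Usp2 at 1.30 (adjusted p = 0.00431), and Prkra was not. The count was also 26 without vehicle 2 h replicate 3, with the majority turned to 8 higher and 18 lower, 3 without vehicle 2 h replicate 2, 3 and 1 without aldosterone 2 h replicates 1 and 2, 9 without vehicle 8 h replicate 3, and 3 without aldosterone 4 h replicate 2, aldosterone 4 h replicate 3 or aldosterone 8 h replicate 3. A fit to the 6 samples of this time alone gave 0 genes, and Prkra, Hes1, Bphl, Zfp52 and Chac1 lost their calls in 18 of 28, 8 of 29, 4 of 28, 2 of 29 and 1 of 29 alternative settings.

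At 4 h, 4 of the 6 measured always-named genes were past the threshold, all higher with aldosterone. Fkbp5 rose 3.73-fold (1.90 ± 0.26, adjusted p = 0.00224), Zbtb16 rose 3.47-fold (1.80 ± 0.19, adjusted p = 0.000154) and Per1 rose 2.66-fold (1.41 ± 0.26, adjusted p = 0.0221). Sgk1 rose 1.9-fold (0.93 ± 0.17, adjusted p = 0.0219). Pgf, placental growth factor, a ligand of the vascular endothelial growth factor receptor Flt1, rose 4.57-fold (2.19 ± 0.41, adjusted p = 0.0249). Without aldosterone 4 h replicate 2, Pgf at 4 h rose by 1.52 and was not past the threshold (adjusted p = 0.0617, from 0.00188 to 0.492 over the alternatives). Krt18, a keratin of simple epithelia, fell to 0.422 of its vehicle level (-1.24 ± 0.18, adjusted p = 0.00307). It was the only fall among 17 genes past the threshold, 16 of them higher. At an unadjusted p under 0.05 there were 267 genes, a smaller share of the 7092 tested than the 0.05 that no effect would give. In all 17 the aldosterone and vehicle samples did not overlap, which selection by p-value on the same samples favours.

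Birc2, an inhibitor of apoptosis, rose 2.25-fold (1.17 ± 0.16, adjusted p = 0.00224) and Sphk1, which makes sphingosine-1-phosphate, rose 2.22-fold (1.15 ± 0.16, adjusted p = 0.00224). The cation channel gene Trpv2 rose 2.25-fold (1.17 ± 0.18) and the transporter gene Slc45a3 rose 2.46-fold (1.30 ± 0.20), each with an adjusted p of 0.00662. Pelp1, a coregulator of nuclear receptors, rose 2.13-fold (1.09 ± 0.19, adjusted p = 0.0175), but a second probe set, below the filter, gave -0.01. Mt1 and Mt2 rose 2.08-fold and 1.86-fold (adjusted p = 0.018 and 0.0437), and Ccn2, a matricellular growth factor, rose 1.42-fold (0.50 ± 0.09, adjusted p = 0.0175).

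As a group, 6 of the 25 corticosteroid response genes rose at 4 h and 0 fell, 12 rose adjusted over the list alone, and the list ranked above other genes (camera adjusted p = 1.39e-22, and 0.00342 with an estimated correlation). Tsc22d3 was at 1.24 ± 0.26 without passing (adjusted p = 0.0748), and Nr3c1 was at -0.2 without passing. Inflammatory mediators and adhesion genes ranked low (adjusted p = 0.00213, and 0.518 with an estimated correlation), with 0 of 20 past the threshold. Heat shock and unfolded protein response genes ranked low as well (adjusted p = 0.0477, and 0.628 with an estimated correlation), with 0 of 16 past it. The circadian clock list had 1 riser of 14, Per1, and the vascular tone and growth signalling list 1 of 16, Pgf, or 2 without vehicle 2 h replicate 1. The count was 8 without vehicle 4 h replicate 3, and 10, 5 and 8 without aldosterone 4 h replicates 1, 2 and 3. It was 32 without vehicle 2 h replicate 1, which enters this difference only through the shared estimate of spread. Calls for Mt2, Sgk1, Ccn2, Pgf, Mt1, Per1, Pelp1 and Slc45a3 were lost in 15, 8, 8, 7, 7, 6, 5 and 3 alternative settings, and those for Sphk1 and Trpv2 in 1 each.

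At 8 h, Zbtb16 rose 7.06-fold (2.82 ± 0.19, adjusted p = 7.15e-08) and Fkbp5 rose 6.96-fold (2.80 ± 0.26, adjusted p = 7.99e-06). Second probe sets gave 1.97 and 2.76, but that of Fkbp5 was dim, with a mean of 2.86 over the 18 samples, so its change is imprecise. Per1 and its clock partner Per2 rose 2.81-fold and 3.47-fold (adjusted p = 0.00551 and 0.000141), though a dimmer Per2 probe set below the filter gave 0.32. Tsc22d3, fitted at 0.79, was not past the threshold, and its vehicle samples lay under the filter level. Lcn2, a siderophore-binding lipocalin, rose 4.27-fold (2.09 ± 0.20, adjusted p = 1.39e-05) from near the filter level, 3.78 ± 0.41 in vehicle to 5.88 ± 0.25 with aldosterone (SD, n = 3). Mt4, a metallothionein of stratified epithelia, rose at least 6.3-fold (fitted 3.30 ± 0.20, adjusted p = 3.07e-08) and was above the filter level only in this group.

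Among the other leading rises at 8 h, Pgf rose 4.59-fold (2.20 ± 0.41, adjusted p = 0.0082) and Birc2 rose 3.77-fold (1.92 ± 0.16, adjusted p = 1.84e-06). Slc10a6, a carrier of sulfated steroids, rose 3.73-fold (1.90 ± 0.38, adjusted p = 0.0145), Cdo1, a cysteine dioxygenase, rose 3-fold, and Serpina3n, an acute-phase protease inhibitor, rose 2.95-fold. Klf9, a Krüppel-like factor, rose 1.78-fold (adjusted p = 0.000717). The cytokine gene Il1b was at least 3.01-fold lower than in vehicle (fitted -1.86 ± 0.42, adjusted p = 0.0387) and Krt18 to 0.412 (-1.28 ± 0.18, adjusted p = 0.000658). The homeobox gene Prrx1, the guidance cue Sema5a, Nrp1, a co-receptor for semaphorins and vascular endothelial growth factor, and the tyrosine kinase gene Tnk2 fell, with log2 changes of -0.78, -0.78, -0.74 and -0.67. The chemokine gene Cxcl12, the adaptor gene Stac, the metalloproteinase inhibitor gene Timp3 and the stress gene Gadd45a fell, with changes of -0.65, -0.63, -0.62 and -0.55 (Stac at least 1.26-fold, ending under the filter level).

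In total 71 genes passed at 8 h, 61 higher and 10 lower, with 444 at an unadjusted p under 0.05. The samples did not overlap in any of the 71, which selection by p-value on the same samples favours. Of the 16 genes higher at 4 h, 13 were also higher at 8 h, against 0.14 for independent lists, where the 2 differences share no sample but share the estimate of spread; Krt18 was lower at both. Corticosteroid response genes numbered 11 risers and 0 fallers of 25, with 13 risers adjusted over the list alone and a list median of 0.55 (camera adjusted p = 1.21e-26, and 0.00162 with an estimated correlation). The matrix and fibrosis list had 2 risers and 0 fallers of 18, or 2 and 2 without vehicle 2 h replicate 1: Ccn2 rose 1.82-fold (0.86 ± 0.09, adjusted p = 1.69e-05) and Lox, which crosslinks collagen and elastin, rose 1.93-fold (0.95 ± 0.18, adjusted p = 0.00928). The inflammatory list had 1 riser, the granulocyte growth factor gene Csf3 at 2.43-fold (adjusted p = 0.0288), and 2 fallers, Il1b and Cxcl12. Of the metallothionein and oxidative stress list, Mt1 at 2.2-fold and Mt2 at 1.93-fold rose, 2 of 19. The list of corticosteroid receptors and renal aldosterone-response genes had 0 of 8 members past the threshold at 2, 4 and 8 h, or 1 at 2 h without vehicle 2 h replicate 1, with Nr3c1 at -0.33 ± 0.15 at 8 h (adjusted p = 0.785). Without aldosterone 8 h replicate 2 the count was 33, and without vehicle 2 h replicate 1 it was 111, which held all 71. Vehicle 2 h replicate 1 is not in the 8 h difference, so the log2 changes stayed the same and only the shared estimate of spread changed. Over the alternative settings tried, calls for Gadd45a, Il1b, Sgk1 (1.69-fold, adjusted p = 0.0335), Csf3, Sema5a, Cxcl12, Nrp1, Stac, Slc10a6, Lox, Mt2, Serpina3n, Prrx1, Cdo1 and Pgf were lost in 23, 11, 10, 8, 7, 6, 5, 5, 4, 3, 3, 3, 2, 1 and 1.

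**Figure D1:**
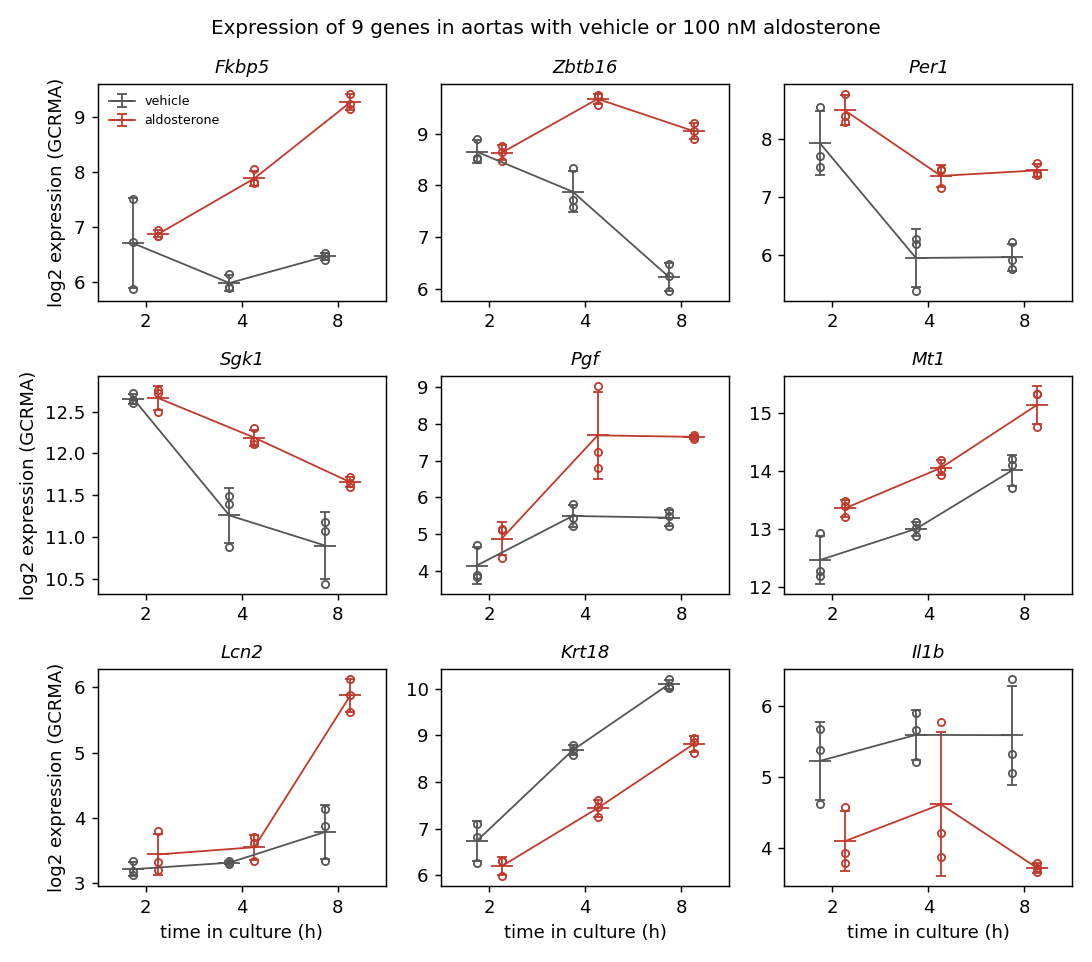
Deposited log2 GCRMA expression (vertical axis) of 9 genes against hours in culture (horizontal axis, evenly spaced), with open circles for the 3 samples per group, dashes and bars for mean ± SD, grey for vehicle and red for aldosterone. Zbtb16 ended at 9.05 with aldosterone against 6.23 with vehicle at 8 h, and Krt18 ended lower with aldosterone, at 8.81 against 10.10.

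**Figure D2:**
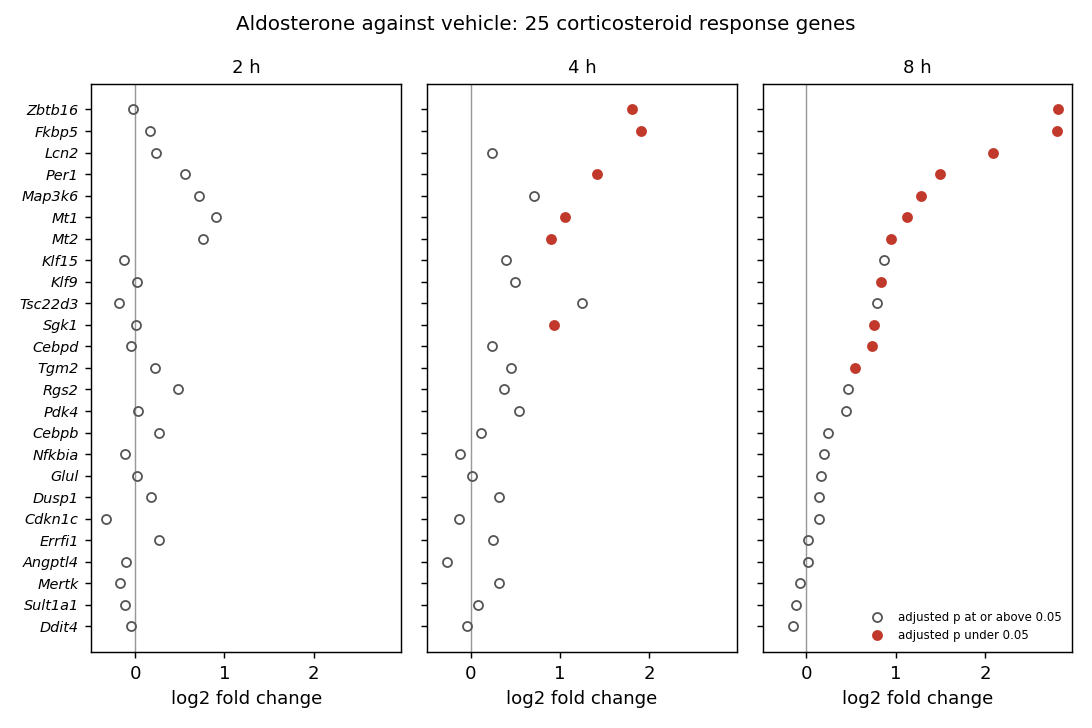
Log2 fold change of aldosterone over vehicle (horizontal axis) for the 25 measured corticosteroid response genes at 2, 4 and 8 h, with filled red circles for genes past the adjusted threshold of 0.05. The number of filled circles is 0 at 2 h, 6 at 4 h and 11 at 8 h.

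Averaged over the 3 times, the hormone effect was estimated from all 18 samples. Pgf rose 3.26-fold (1.71 ± 0.24, adjusted p = 0.000502), Fkbp5 rose 3.08-fold (1.62 ± 0.15, adjusted p = 7.49e-06), Birc2 rose 2.46-fold (1.30 ± 0.09, adjusted p = 2.22e-07) and Sphk1 rose 2.21-fold (1.15 ± 0.09, adjusted p = 1.12e-06). Mt1 rose 2.04-fold (1.03 ± 0.11, adjusted p = 2.56e-05), with a second probe set at 1.26. Slc10a6, Per1, Trp53inp1, a p53-induced gene, Cdo1 and the kinase gene Map3k6 rose 2.45-fold, 2.23-fold, 2.11-fold, 2.02-fold and 1.87-fold. For Trp53inp1 this is 1.08 on the log2 scale, and a second, dimmer probe set gave 0.34. Il1b fell (adjusted p = 0.00748), at -1.19 on the log2 scale with values under the filter level set to it, and Krt18 fell to 0.493 of vehicle (-1.02 ± 0.10, adjusted p = 1.92e-05).

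Smaller averaged falls followed. Tgif1, a homeobox repressor of TGF-beta signalling, the Wnt receptor gene Fzd7, the cytokine gene Il11 and the metalloproteinase gene Adam19 fell, with log2 changes of -0.59, -0.57, -0.56 and -0.50. Tnk2, Prrx1, Nrp1 and Nabp1, a single-stranded DNA binding gene, fell, with changes of -0.50, -0.47, -0.46 and -0.46; the 2 other Nabp1 probe sets gave -0.12 and -0.34. In all, 78 genes passed, 61 higher and 17 lower, 66 of them with the same sign at each time; 598 had an unadjusted p under 0.05. Corticosteroid response genes contributed 10 risers and 0 fallers of 25 (18 risers adjusted over the list alone, camera adjusted p = 2.55e-28, and 0.00122 with an estimated correlation), and Zbtb16 averaged 2.89-fold. Sgk1 averaged 0.56 on the log2 scale and passed. Nr3c1, at -0.22, did not pass, nor did Tsc22d3, fitted at 0.62 with its 8 h vehicle samples under the filter level. The inflammatory list had 2 fallers of 20, Il1b and Cxcl12 (camera adjusted p = 0.0174, and 0.705 with an estimated correlation). In the cell cycle list 1 of 6 rose, the kinase inhibitor gene Cdkn1a at 1.27-fold (adjusted p = 0.0307), and in the hypoxia and glycolysis list 0 of 15 passed. Without vehicle 2 h replicate 1 the count was 146, which held all 78. Alternative settings ended the calls of Cdkn1a, Adam19, Cxcl12, Fzd7, Tgif1, Nabp1 and Prrx1 in 15, 13, 12, 9, 9, 2 and 1 cases.

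The size of the aldosterone effect was then compared between times. It differed for 11 genes (420 at an unadjusted p under 0.05). Zbtb16 and Fkbp5 responded more at 8 h than at 2 h, by 2.84 ± 0.26 and 2.63 ± 0.37 on the log2 scale (adjusted p of the 3-time test 5.92e-05 and 0.00669). Ccn2 differed by 0.87 ± 0.12 (adjusted p = 0.00681). Mt4, Lcn2 and Lrrc49 also responded more at 8 h (adjusted p = 2.98e-06, 0.00606 and 0.00512), but groups of each lay under the filter level, and with values set to at least that level the differences were 2.65, 1.83 and 0.55. Plxna2, a semaphorin receptor, Asph, an aspartyl hydroxylase, and Nudt4, a phosphohydrolase of inositol pyrophosphates, differed by 0.90, 1.21 and 1.07 in the same direction. Chac1 went the other way (adjusted p = 0.000736), with a difference of -0.57 when its vehicle values at 2 h, under that level, are set to it. Calls for Asph, Ccn2, Nudt4 and Plxna2 ended in 2, 2, 2 and 1 of the alternative settings.

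Far more genes differed between times of vehicle culture, without hormone, than between aldosterone and vehicle. Time in culture was not separated from anything else that differs between these times. In vehicle samples between 2 and 8 h, the neutrophil chemokine gene Cxcl5 rose 158-fold (7.30 ± 0.33, adjusted p = 1.11e-11). Psat1, Shmt2 and Mthfd2, enzymes of serine synthesis and folate metabolism, rose 80.4-fold, 66.2-fold and 35.8-fold. Car9 and Egln3, hypoxia-induced genes, rose 57.2-fold and 57-fold, and Chac1 and Trib3, targets of ATF4, rose at least 25.7-fold and 47.6-fold. The amino acid transporter gene Slc7a5 and the long non-coding RNA Pvt1 rose 31.8-fold and at least 14.3-fold. The immediate early gene Fosb fell at least 239-fold (adjusted p = 6.93e-15), from 11.90 to 2.90, under the filter level, and Fos, Nr4a1 and Klf2 changed by -5.56, -5.16 and -5.05 on the log2 scale. Muscle genes Xirp1 and Tcap changed by -5.39 and -5.17, and the interferon-induced Ifit1, the neuropeptide Y receptor gene Npy1r, the transporter gene Abca8a and the cytoglobin gene Cygb changed by -5.34, -5.32, -4.89 and -4.78; Tcap, Ifit1, Npy1r and Cygb ended under the filter level, at least 13.9-fold, 17.4-fold, 15.9-fold and 21-fold lower.

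In total 4150 genes differed between 2 and 8 h of vehicle culture, 1888 higher and 2262 lower. Every one of 15 measured hypoxia and glycolysis genes rose, including the glucose transporter gene Slc2a1 at 6.67-fold and Ndrg1 at 6.8-fold (camera adjusted p = 2.03e-10, and 0.152 with an estimated correlation). Of 18 immediate early genes 14 fell and 2 rose (adjusted p = 4.35e-07, and 0.246 with an estimated correlation). Clock genes fell in 11 of 14 cases, with 1 riser (adjusted p = 0.011, and 0.331 with an estimated correlation); Per1, Per2 and Hlf fell, with log2 changes of -1.96, -2.23 and -3.34 (Hlf at least 5.7-fold, ending under the filter level). Of 20 inflammatory genes 11 rose, among them Lif at 10.8-fold and Csf1 at 3.85-fold, and 4 fell, including Socs3 at -1.94 (adjusted p = 0.0136, and 0.445 with an estimated correlation). The metallothionein and oxidative stress list had 11 risers, with heme oxygenase gene Hmox1 at 9.85-fold and the cystine transporter gene Slc7a11 at least 3.55-fold higher, and 4 fallers of 19, including the oxidase gene Nox4 at -2.60 (adjusted p = 0.0136, and 0.445 with an estimated correlation). Corticosteroid response genes went both ways, 8 rising and 13 falling of 25 (camera adjusted p = 0.22): Zbtb16 fell by 2.42 and Mertk, a phagocytic receptor, rose 4.56-fold. By fry, which does not rank a list against other genes, this list was lower at 8 h (fry adjusted p = 0.000119).

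The remaining pathway lists were not past the camera threshold between 2 and 8 h, although single members moved. Timp1 and Mmp3, regulators of matrix breakdown, rose 21.1-fold and 10.5-fold in a list with 4 risers and 10 fallers of 18, Ccn2 and Col1a2 falling to log2 changes of -1.33 and -1.56 (adjusted p = 0.283). Endothelin gene Edn1 fell by 3.52 in the vascular list, which had 4 risers and 7 fallers of 16 (adjusted p = 0.338). Heat shock and unfolded protein response genes had 9 risers, such as Asns at 27.3-fold, and 5 fallers, such as Hspa1a at -3.61 (adjusted p = 0.0933). Renal and receptor genes had 2 risers and 4 fallers of 8 (camera adjusted p = 0.418, but lower by fry with adjusted p = 0.0102), and cell cycle genes 2 and 1 of 6 (camera adjusted p = 0.665).

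At 4 h of vehicle culture, against 2 h, 2852 genes differed, 1038 higher and 1814 lower. Psat1, Cxcl5 and Egln3 rose 23.3-fold, 22.4-fold and 18.5-fold, and Chac1 and Pvt1, under the filter level at 2 h, rose at least 25.7-fold and 8.78-fold. The brown fat gene Ucp1, the flow-responsive factor Klf2, the clock output gene Dbp, the imprinted non-coding RNA Rian and the steroid-inducible Ras gene Rasd1 fell, with log2 changes of -3.97, -3.67, -3.41, -3.37 and -3.21 (Rasd1 at least 6.41-fold, ending under the filter level). Hypoxia and glycolysis genes had 13 risers of 15 (adjusted p = 2.16e-12, and 0.0889 with an estimated correlation) and immediate early genes 14 fallers and 2 risers of 18 (adjusted p = 3.63e-07, and 0.235 with an estimated correlation). Inflammatory genes had 9 risers and 4 fallers (adjusted p = 2.42e-05, and 0.235 with an estimated correlation), or 10 and 2 without vehicle 2 h replicate 1, and heat shock and unfolded protein response genes 9 and 2 (adjusted p = 0.000303, and 0.235 with an estimated correlation). The circadian clock list and the metallothionein and oxidative stress list were not past the threshold at 4 h (adjusted p = 0.343 and 0.509). The median change of all genes was -0.08 at 8 h and -0.13 at 4 h, and centring every sample on its median moved the 4 h value to 0.02 and the split to 1512 higher and 1491 lower. Without vehicle 2 h replicate 1 the splits were 2297 higher and 2030 lower at 8 h, and 1426 and 1399 at 4 h; a fit to the 6 samples alone gave 1331 genes at 4 h.

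**Figure D3:**
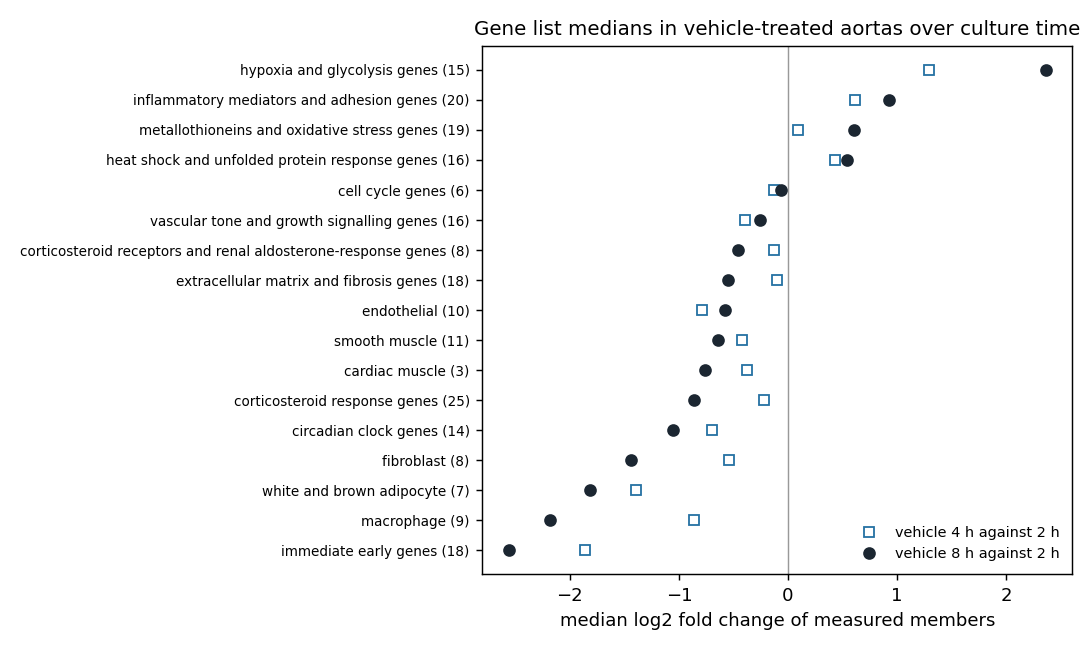
Median log2 change (horizontal axis) of the measured members of 17 gene lists in vehicle samples, at 8 h (filled circles) and 4 h (open squares) against 2 h, with the number of measured genes in brackets. Hypoxia and glycolysis genes lie highest, at 2.36 for 8 h, and immediate early genes lowest, at -2.56.

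Markers of the cell types that an excised aorta can hold were examined in the same comparisons. Between 2 and 8 h of vehicle culture, 7 of 9 macrophage markers fell and 1 rose, with Mrc1, the mannose receptor, at -3.52 on the log2 scale (camera adjusted p = 0.0136, and 0.445 with an estimated correlation). Of 8 fibroblast markers 7 fell, Pi16 at -1.99 (adjusted p = 0.00236, and 0.445 with an estimated correlation), of 7 adipocyte markers 6 fell, Lpl at -2.62 (adjusted p = 0.0136, and 0.445 with an estimated correlation), and of 11 smooth muscle markers 7 fell and 1 rose, Cnn1 at -1.88 (adjusted p = 0.017, and 0.445 with an estimated correlation). Among 10 endothelial markers 5 fell and 0 rose, or 5 and 2 without vehicle 2 h replicate 1, with Kdr at -2.20 (adjusted p = 0.17), and 0 of 3 cardiac muscle genes passed. Vehicle 2 h replicate 1, in the baseline group, exceeded its mates by a median of 0.93 over the macrophage list and 0.80 over the adipocyte list, against 0.42 over all genes; without it, 6 markers of each list fell by 8 h. By 4 h, 6 of 7 adipocyte markers had fallen (adjusted p = 0.0104, and 0.68 with an estimated correlation).

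With aldosterone, 1 cell type marker passed at any time: Mrc1 rose 2.41-fold at 8 h (1.27 ± 0.28, adjusted p = 0.0335), when 1 of 9 macrophage markers rose and 0 fell (camera adjusted p = 0.544); its call was lost in 7 of 29 alternative settings. The 3 measured cardiac muscle genes ranked high at 8 h (adjusted p = 0.036, and 0.737 with an estimated correlation) with 0 past the threshold, Tnnt2 at 1.09 ± 0.46. Adipocyte markers ranked high in the average over times (adjusted p = 0.0174, and 0.705 with an estimated correlation), with 0 of 7 past it. Smooth muscle, endothelial and fibroblast markers had 0 members past the threshold at 2, 4 and 8 h, with adjusted p of 0.0716, 0.72 and 0.0716 at 8 h. Lymphocyte, Schwann cell, skeletal muscle, red blood cell and mesothelial lists had 1, 1, 0, 2 and 0 measured genes and were not tested; of these 4 genes, S100b and Slc4a1 fell in vehicle by 8 h, with log2 changes of -0.82 (at least 1.66-fold, ending under the filter level) and -1.73, and Ms4a1 and Alas2 were not past the threshold.

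RNA integrity was read from the array's own control probe sets. The 3' minus 5' signal of Gapdh was 0.545 with aldosterone and 0.549 with vehicle, a difference of -0.004 (exact two-sided permutation p = 0.916 over 8000 relabellings within times, n = 9 per treatment). For beta-actin it was 1.85 and 1.90 on the same scale, a difference of -0.05 (exact two-sided permutation p = 0.549). Over the 18 samples the Gapdh value ranged from 0.36 to 0.79. Across times it was 0.609 ± 0.046, 0.583 ± 0.146 and 0.449 ± 0.059 at 2, 4 and 8 h (SD, n = 6), and beta-actin was 1.89 ± 0.187, 1.96 ± 0.115 and 1.77 ± 0.166. The 3 vehicle samples of 8 h, at 0.355 to 0.528 for Gapdh, lay below the 3 of 2 h, at 0.559 to 0.645, so the culture comparisons carry this difference, which was not tested.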

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

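Of the tests below, the splits and the test on other probe sets were set before their results were seen, and the tests of RNA degradation, brightness offset, spread, growth with time, cross-hybridization and scatter were chosen afterwards.

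The aldosterone effect differed between times for 11 genes by the F test. Given as the effect at 8 h minus that at 2 h, the fitted values were 3.50 for Mt4, 2.84 for Zbtb16, -1.66 for Chac1, 1.56 for Lrrc49, 1.87 for Lcn2, 2.63 for Fkbp5, 0.90 for Plxna2, 0.87 for Ccn2, 1.21 for Asph and 1.07 for Nudt4. Cep85, at 1.69, was the 11th and is named here after its value was seen; with Mt4, Chac1 at 2 h, Lrrc49 and Lcn2 it lies near or under the filter level; with values under 4 set to 4 the differences were 2.65 for Mt4, -0.57 for Chac1, 0.55 for Lrrc49, 1.83 for Lcn2 and 1.34 for Cep85. Among 100 relabellings within times, 2 gave as many genes, the real one included, and the highest other gave 16, a share under 0.05, although that other relabelling gave more genes than the real one.

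Probe sets without a single named gene, which the comparisons of genes leave out, also held differences. Of 1045 such probe sets tested together with all 12281, 2 were past the threshold at 4 h, both higher (largest 2.06), and 9 at 8 h, all higher (largest 4.21). At 2 h limma gave 0, with 137 at an unadjusted p under 0.05.

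For the counts at single times, 3 samples against 3 allow 10 splits, too few for a share under 0.05. At 2 h, 2 of the 10 splits gave as many genes, the real one with 5 and another with 6. At 4 h, 8 h, vehicle 8 h against 2 h and vehicle 4 h against 2 h, 1 of the 10 did, with real counts of 17, 71, 4150 and 2852 and highest others of 2, 2, 2 and 0. For the average over times 1 of 100 drawn relabellings, the real one, gave 78 genes and the highest other gave 4. For that average, a chance split of the samples is argued against, although 100 draws cannot exclude it. The 10 splits cannot decide this for the single comparisons. A mixed split also puts any real difference into the spread, which lowers its count.

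Vehicle 2 h replicate 1 lay far from its group mates, with a median deviation of 0.419 and an SD of deviation of 0.645, against at most 0.341 in other groups. RNA degradation is argued against, since the larger of its 2 control margins over the highest other sample was -0.162. An offset of brightness is argued against as the whole cause: quantile normalization lowered the median deviation to 0.092 and the genes off by more than 1 log2 from 908 to 573, against at most 122 in other groups. Of its genes, 82 were more than 2 log2 lower than in its mates, and the 79 other probe sets of 47 of them deviated by a median of 0.294 (quartiles -0.073 and 0.607), and 3 of 79 were more than 2 lower, so faults of single probe sets on that array may account for these low values. The many higher values are not covered by that test, and no biological explanation was tested.

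Fewer genes passed the adjusted threshold at 2 h than at 8 h, while the order was the other way at an unadjusted p under 0.05 (782 and 444) and with 1.5-fold added (259 and 188). The spread of the 2 h vehicle group alone is argued against as the whole cause, since without vehicle 2 h replicate 1 the ratio of genes at 2 h to genes at 8 h was 29 to 111, and with 1 vehicle 8 h sample left out as well, to even the group sizes, it was at most 0.389. A response that grows with time may contribute: the mean effect over the corticosteroid list was 0.144, 0.529 and 0.745 at 2, 4 and 8 h, and 0.278 at 2 h without vehicle 2 h replicate 1. The difference of 0.601 between 8 and 2 h had an exact two-sided permutation p of 0.085 over 400 relabellings (smallest possible 0.005) and a fry p of 0.000761. The 2 tests fall on different sides of the threshold, so this stays open, and the rule for it was refined after the values were seen.

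Mt4 was at 6.65 ± 0.09 (SD, n = 3) with aldosterone at 8 h and at 2.89 to 3.35 in the other 5 group means. The lowest of the 3 samples exceeded the highest of the other 15 by 2.773. Mt4 was flagged from these same values, so this gap gives no separate evidence against scatter near the background. Cross-hybridization of the abundant Mt1 or Mt2 transcripts could raise it, and the number of other groups whose Mt1 level reached that of aldosterone at 8 h was 0 (15.15 there, at most 14.06 elsewhere). Mt4 induction and cross-hybridization cannot be told apart here, because the highest Mt1 level and the Mt4 signal fall in the same group.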

How the results depend on the processing

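The values without vehicle 2 h replicate 1 were also examined as a test chosen after that sample was seen to diverge; the other alternatives were planned. Over 493 named results and 14134 values, 0 reversed direction past the threshold, 95 not past it under either setting changed sign, and calls weakened in 232 leave-one-out and 91 other values and appeared in 41 and 59. Many of these values could not change sign, because the setting left the compared group means as they were. Examples are a changed prior, a replicate block, or leaving out a sample of a group not compared. The number of values therefore overstates how far direction was tested. The count of 5 at 2 h was 17 without filter, 2 with the filter at 6, 8 with all probe sets, 10 with mean of probe sets, 8 with quantile normalization, 10 with median centring, 54 with array weights, 0 in limma on only the samples compared, 259 at unadjusted p and 1.5-fold, and 1 to 29 over single samples left out. The count of 17 at 4 h was 11 without trend, 9 without filter, 27 with all probe sets, 42 with array weights, 8 with only the samples compared, 94 at unadjusted p and 1.5-fold, and 5 to 32 over samples left out. The 71 at 8 h became 120 with all probe sets, 222 with array weights, 188 at unadjusted p and 1.5-fold, and 33 to 111 over samples left out. The averaged 78 became 149 with all probe sets, 260 with array weights, 32 at adjusted p and 1.5-fold, and 53 to 146 over samples left out. The 11 differing between times became 23 and 29 with all probe sets and array weights, vehicle 8 h 6851 with all probe sets, and vehicle 4 h 4380 with all probe sets and 1331 with only the samples compared. All probe sets test more items, only the samples compared use fewer samples, and the fold rules change the threshold; elsewhere the cause was not tested. List tests past the threshold numbered 25, 3 with estimated correlation and 29 with fry. In the aldosterone comparisons, fry passed only corticosteroid response genes at 4 h, 8 h and averaged (fry adjusted p = 0.00152, 5.68e-05 and 1.69e-05). The other aldosterone list calls by camera were lost with fry. At 2 h fry gave adjusted p of 0.85, 0.205 and 0.32 for corticosteroid response, immediate early and inflammatory genes.

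The higher and lower split at 2 h, 3 and 2, was 7 and 1 with quantile normalization and 8 and 2 with centring, but 8 and 9 without filter, 111 and 148 at unadjusted p and 1.5-fold, and 8 and 18 without vehicle 2 h replicate 3; at vehicle 4 h, 1038 and 1814, it was 1366 and 1689, and 1512 and 1491. What background limits in dim genes was not tested apart from the filter, which also changes how many genes are tested: counts at 2, 4 and 8 h were 17, 9 and 57 without it and 2, 16 and 65 with it at 6.

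With the replicate number as a fixed or random block, counts were 5 and 4 at 2 h, 18 and 15 at 4 h, 67 and 66 at 8 h, 76 and 76 averaged, 10 and 11 differing between times, 4121 and 4110 for vehicle 8 h, and 2818 and 2797 for vehicle 4 h. Pair correlations ran from -0.19 to 0.28, and 7 of 18 samples correlated best with their own number.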

Other observations

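Both tests in this part were chosen after the results at 8 h were seen.

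Some aldosterone-raised genes, such as Zbtb16 and Sgk1, were lower at later times of vehicle culture. In vehicle, Zbtb16 went from 8.65 at 2 h to 7.88 at 4 h and 6.23 at 8 h, while with aldosterone it was 8.63, 9.68 and 9.05. Sgk1 went from 12.65 to 11.26 and 10.90 in vehicle and from 12.66 to 12.19 and 11.66 with aldosterone, so its level fell in culture with either treatment. Fkbp5 showed no steady fall, at 6.71, 5.99 and 6.47 in vehicle, and rose with aldosterone from 6.88 to 7.89 and 9.27.

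Whether genes raised by aldosterone at 8 h tend to decline in vehicle culture was tested on vehicle samples of 2 and 4 h, whose means do not enter that difference but whose spread enters the choice of its genes. Of the 61 genes, 22 fell and 11 rose past the threshold, against 1814 and 1038 of all 7092 genes. Their median change of -0.223 was at percentile 7.82 of 10000 random lists of the same size (median -0.094, 2.5th percentile -0.275). Without vehicle 2 h replicate 1 the median was -0.148, at percentile 3.86. A decline of these genes in culture could therefore be neither shown nor excluded, and the rule for it was refined after the values were seen.

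Genes called at 8 h may respond in the same direction earlier. The mean effect at 2 and 4 h of the 71 genes, signed by their direction at 8 h, was 0.354 (0.19 at 2 h and 0.519 at 4 h), with an exact two-sided permutation p of 0.005 over 400 relabellings, the smallest they can give. The sign was the same for 49 of 71 genes at 2 h and 66 of 71 at 4 h, in samples whose means the 8 h difference does not use, although their spread helped to choose the genes; this is consistent with a response shared between times.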
